A study of Mus musculus with 2 samples.

How the data were processed

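RNA from whole mouse embryos at 8.5 days post coitum (dpc) was measured on the Affymetrix mouse array that the sample titles call 430. One array carried RNA from embryos with maternal uniparental disomy of chromosome 18 (matUPD18) and 1 array carried RNA from embryos with the paternal disomy (patUPD18). The number of embryos behind each RNA is not given in the sources used here. Per the labels' protocols, total RNA was amplified with a RiboAmp kit, labelled with biotin, fragmented and hybridised. Amplification of this kind copies RNA from its 3' end, so probe sets far from the 3' end of a transcript can read low.

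The deposited values are MAS5 signal intensities, 1 per probe set and array, made with MAS5/GCOS per the submitters' processing notes; versions are not given in the sources used here. The table holds 45101 probe sets. The 2% trimmed mean of the deposited intensities was 500.003 on the matUPD18 array and 500.004 on the patUPD18 array, so each array had been scaled to a common target. No detection calls were used here, and no further normalization between the arrays was applied for the main values. This scaling fixes the mean level of each array, so a shift shared by most transcripts could not be seen.

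Of the probe sets, 34958 had exactly 1 gene symbol in the platform annotation, 932 had several, 9160 had none listed, and 64 were Affymetrix control probe sets. Symbols were updated through the Entrez identifier, which matched the mouse RefSeq gene table (GRCm38.p6) for 34754 probe sets. The genome build behind the array annotation is not given, so that table was used for symbols, chromosome, gene order and gene length only, and no coordinates are reported. Each of 18193 genes was represented by its probe set with the highest mean signal. Signals below an array's 40th percentile (84.2 on the matUPD18 array and 82.5 on the patUPD18 array) were raised to it before taking log2. A gene was called measurable where the higher of its 2 signals reached its array's 60th percentile (190.1 and 184.9), which left 10484 genes. Log2 ratios are matUPD18 over patUPD18, and folds are the higher signal over the lower; where the lower signal lay under the floor, the fold is given as "at least".

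With 1 array per group no test between the groups was possible, and no p-value or standard error is given. Counts use a 2-fold threshold. As a measure of technical disagreement, the log2 ratios of measurable probe sets of the same gene had a pooled standard deviation of 0.44 (10214 probe sets of 4005 genes). This describes these arrays and does not include differences between embryos. For 30 gene lists fixed before the data were examined, and for each chromosome, the median log2 ratio was placed among the medians of random lists of the same size matched on mean signal in 20 groups. There were 10000 random lists for each gene list and for chromosome 18, and 2000 for each other chromosome. These percentiles describe the 2 libraries and are not tests of the genotypes. A list needed 5 measurable genes. Of the 927 list entries, 824 had a gene on the array; the alias Nesp was read as Gnas. Genes sit in more than 1 list where tissues share them.

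Genes were named by a rule fixed at the same time as the lists: Impact, the 12 largest ratios in each direction, the 8 largest in each direction on chromosome 18, the 3 measurable genes on each side of Impact, up to 2 examples per direction of each list with more for lists outside the central 95% of random lists, every measurable Y-linked gene and the array's control probe sets. The rule gave 146 genes. A further 19 were chosen after their values were seen: Rbp4, Amn, Slc2a2, Hemgn, Gata1, Klf1, Alas2, Hba-x, Hbb-bh1, Hbb-y, Ier3, Dnajb1, Hoxd8, Msgn1, Kdm6a, Ftx, Ddx3x, Eif2s3x and Kdm5c. The probe sets without a gene in the closing section were also chosen in this way. Alternatives fixed in advance were other scalings (median centring, quantile, loess), other floors, other probe set rules, other fold thresholds and random lists drawn off chromosome 18. Gene length matching and the omission of yolk sac or red cell genes were added after seeing the data.

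The procedure was tested on simulated data for this pair of arrays, with 10387 measurable genes, 200 genes changed, and a noise standard deviation on the log2 ratio of 0.44, that between probe sets of a gene. At the 2-fold threshold it recovered 37 of 67 genes changed 2-fold, 67 of 67 changed 4-fold and 66 of 66 changed 8-fold. It passed 263 of 10156 unchanged genes (2.59%). The same noise was used at every signal level, whereas the real ratios spread more among dim genes. A log2 ratio of -1.09 (Rasgrf1) ranked 108th in size among the 525 dimmest genes. One of -0.77 (Rps26) ranked 4th among the 524 brightest. These rates therefore do not hold for each signal level. A list shifted by 0.8 was placed outside the central 95%, as were 2 of the 27 other lists. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.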

Results

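Mouse embryos that inherited both copies of chromosome 18 from the mother (matUPD18) were compared with embryos that inherited both from the father (patUPD18). Such embryos have the normal number of chromosomes, so a gene on chromosome 18 that is read from only one parental copy is expected to be silent in one kind and active from both copies in the other. RNA from whole embryos at 8.5 dpc was profiled on 1 array per genotype, with age and tissue matched. There were no replicate arrays, so no difference below could be set against the spread between embryos, and the single array per genotype limits the precision of every value. Signals ranged up to 34954 on the matUPD18 array and 46322 on the patUPD18 array, with medians of 125.4 and 122.0. The log2 signals of the arrays correlated with Pearson's r = 0.93 across the 45101 probe sets, which are not independent replicates.

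The 3' control probe set of Gapdh read 33.95 times the 5' probe set in matUPD18 and 36.4 times in patUPD18, and the corresponding values for beta-actin were 35.7 and 39.3. Such ratios are a measure of RNA quality, but here they also carry the 3' bias of the amplification and cannot be read as quality alone. Probe sets far from the 3' end can therefore read low on both arrays. The 9 bacterial and phage hybridisation controls (BioB, BioC, BioDn and Cre) were all lower on the matUPD18 array under the deposited scaling and the 3 other scalings tried, with a deposited median log2 ratio of -0.50 and a range from -0.75 to -0.41. This shift was larger than the Hox, respiratory chain and heat shock list medians below (-0.42, -0.33 and -0.32). The directions of those medians, and the 2-fold counts, therefore rest on scaling the arrays to a common level. No scaling to these controls was tried.

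Impact, the known paternally expressed imprinted gene of mouse chromosome 18, which encodes an inhibitor of the amino acid sensing kinase GCN2, was 7.51-fold lower in matUPD18. Its signal was 328.4 in matUPD18 and 2466 in patUPD18. This was the largest ratio among the 524 genes of similar mean signal and, with low signals raised to the floor, the 9th largest in size of all 10484 measurable genes. Without the floor it ranked 24th, with most of the genes above it having a lower signal under the floor. The direction is that expected for a gene silent on maternal copies and is the check on the sample labels. The other 2 Impact probe sets did not show it. One read 268.2 in matUPD18 and 205.3 in patUPD18, and the other, below the measurable limit on both arrays, read 97.3 and 52.5. The Impact log2 ratio was -2.91 by the brightest probe set and -1.26 as the median over the 2 measurable ones.

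Across the transcriptome, most genes lay within 2-fold. Of the measurable genes, 283 were at least 2-fold higher in matUPD18, 187 were at least 2-fold higher in patUPD18, and 10014 (95.5%) lay within 2-fold. In simulated arrays with noise as large as that between probe sets of a gene, 263 of 10156 unchanged genes (2.59%) passed 2-fold. Noise of that size could account for a large part of the 283 and 187 genes here. The share itself was not measured. The simulated noise was the spread between probe sets, not between arrays, and was the same at every signal level. The median log2 ratio was -0.04, with an interquartile range from -0.31 to 0.26. With the floor at the 60th percentile, 78 genes were at least 2-fold higher in patUPD18.

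The genes highest in matUPD18 were dominated by products of visceral endoderm, the absorptive and secretory epithelium of the yolk sac. Of the 12 largest ratios in this direction, 10 belonged to the yolk sac and visceral endoderm list. Apoa1, an apolipoprotein, was at least 16.6-fold higher, and its 3 other measurable probe sets had the same direction. Apom was at least 9.17-fold higher by its brightest probe set, while its other measurable probe set had a log2 ratio of only 0.37. Apoa4 was at least 7.20-fold and Apoc2 at least 6.73-fold higher. Ttr (transthyretin, the thyroid hormone carrier) was 8.88-fold higher, with signals of 11979 and 1349, and Afp (alpha-fetoprotein) was 6.64-fold higher, with signals of 12717 and 1914 by its brightest probe set and larger log2 ratios of 3.21 and 4.49 by the other 2 measurable ones. Cubn, the cubilin receptor, was at least 8.37-fold higher, the tight junction gene Cldn2 at least 8.66-fold, Apob 6.26-fold and Spink1 5.72-fold. The remaining 2 genes, not on that list, were X-linked, as was Cldn2. Xist, the RNA that coats the inactive X chromosome, was 12.2-fold higher, and Trap1a was at least 5.65-fold higher.

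The genes highest in patUPD18 were led by the inducible heat shock genes. Hspa1b was 12.2-fold higher in patUPD18, with signals of 618.5 in matUPD18 and 7529 in patUPD18, and both of its other measurable probe sets had the same direction. Hspa1a was at least 11.5-fold higher; these genes are near-identical copies, so their probe sets may not separate them. Impact came next among floored ratios, while 10 genes had larger ratios in this direction without the floor. The circadian repressor Nfil3 was 4.49-fold higher, with signals of 353.5 and 1587. Rad9a, of the DNA damage checkpoint, was at least 4.53-fold higher in patUPD18, and Lce1h at least 4.16-fold. Gpaa1, which attaches glycosylphosphatidylinositol anchors, was 4.47-fold higher by its brightest probe set, while its 2 other measurable probe sets had the opposite direction. Svep1 was 3.73-fold, the corticotropin-releasing hormone receptor Crhr2 at least 3.64-fold, Taf9b 3.38-fold, the potassium channel Kcnn4 3.37-fold and Rab11fip3 3.32-fold higher in patUPD18.

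**Figure D1:**
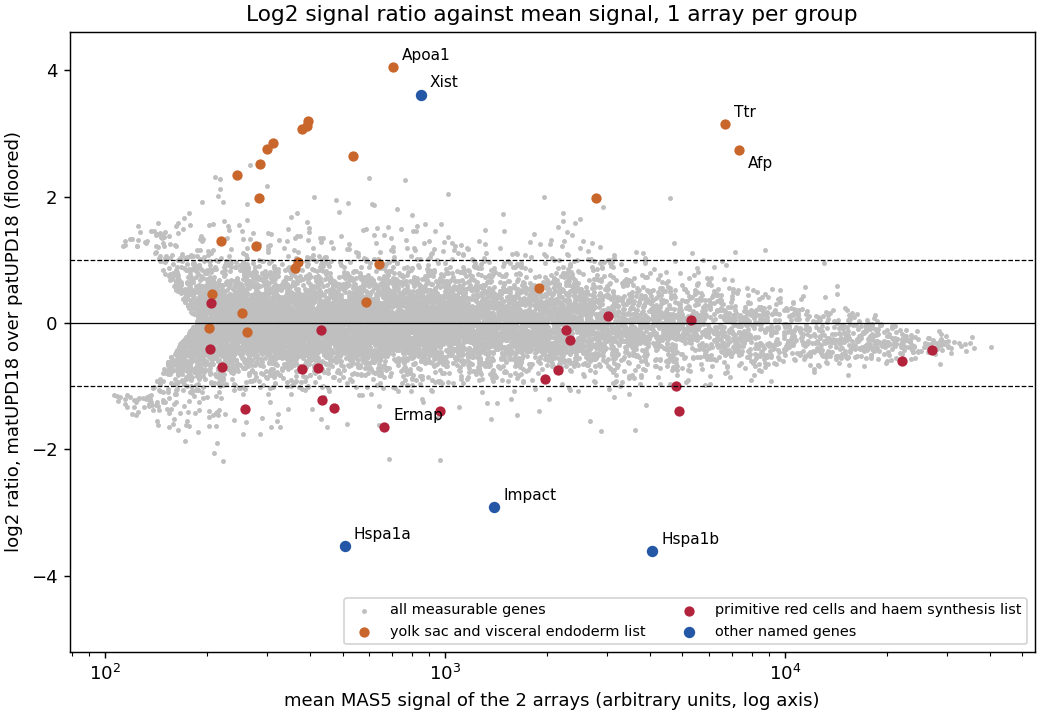
Log2 ratio of matUPD18 over patUPD18 (vertical axis, after flooring) against the mean MAS5 signal of both arrays (horizontal log axis, arbitrary units), 1 point per measurable gene from 1 array per genotype, with dashed lines at 2-fold. Yolk sac genes (orange) reach 4.05 for Apoa1, red cell genes (red) lie mostly below 0, and Impact lies at -2.91.

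On chromosome 18, Impact was the only gene at least 2-fold higher in patUPD18 among 269 measurable genes, each read by its brightest probe set. The next in that direction were Dym (1.94-fold), Pik3c3 (1.89-fold), Ccny (1.86-fold), Tpgs2 (1.83-fold), Mapre2 (1.80-fold), Stard4 (1.77-fold) and Nrg2 (1.73-fold). Of these, Mapre2 had 2 of 3 other measurable probe sets, Ccny 1 of 3 and Stard4 both of its other 2 in the opposite direction. The other 2 of Ccny had log2 ratios of only -0.31 and -0.08. For Csf1r, also on chromosome 18, a dimmer measurable probe set read 96.0 in matUPD18 and 253.7 in patUPD18. Its brightest and its other measurable probe set had log2 ratios of only 0.06 and -0.05. In the other direction 11 genes were at least 2-fold higher in matUPD18. Ttr and Spink1, both on the yolk sac list, led them. The gene 4930503L19Rik followed at 3.85-fold, then the growth factor gene Hbegf (3.33-fold), the nucleic acid binding gene Pura (3.10-fold), the RNA-binding ubiquitin ligase Mex3c (2.45-fold), the kinase Map3k2 (2.28-fold) and the desmosomal cadherin Dsc2 (2.24-fold). The 1 other measurable probe set had the same direction for each of 4930503L19Rik, Hbegf and Pura, but with log2 ratios of only 0.50 for 4930503L19Rik and 0.44 for Hbegf.

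The genes flanking Impact did not share its ratio. In gene order, Npc1 (1.17-fold higher in matUPD18), Ttc39c (1.12-fold higher in patUPD18) and Osbpl1a (1.17-fold higher in matUPD18) precede it among measurable genes. Zfp521 (1.21-fold higher in matUPD18), Ss18 (1.06-fold higher in patUPD18, but higher in matUPD18 after quantile or loess scaling) and Taf4b (1.94-fold higher in matUPD18) follow it.

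Chromosome 18 as a whole did not hold more genes at least 2-fold apart than other genes of like signal. Its 12 genes (4.46%) lay at percentile 69.0 of random lists, whose central 95% ran from 5 to 17. The chromosome's median log2 ratio was 0.05, at percentile 99.7 of random lists (central 95% from -0.10 to 0.02). This was not peculiar to chromosome 18, since 8 of 20 chromosomes had medians outside their central 95%, with 6 above (1, 3, 14, 16, 18 and X) and 2 below (4 and 7). With random lists matched also on gene length, the chromosome 18 median lay at percentile 97.3, inside the central 95%.

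**Figure D2:**
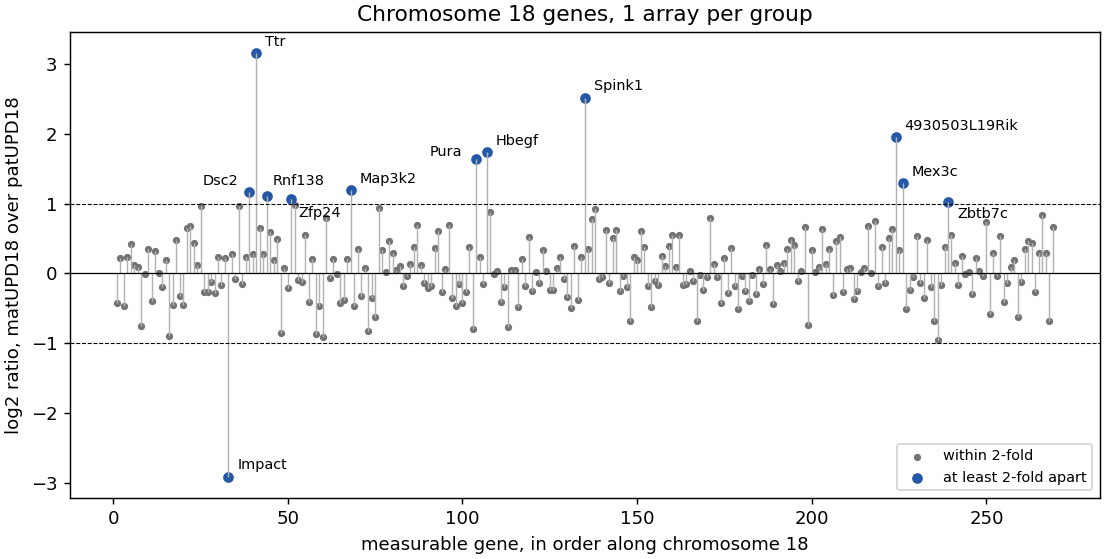
Log2 ratio of matUPD18 over patUPD18 (vertical axis) for the 269 measurable genes of chromosome 18 in gene order (horizontal axis), 1 array per genotype, with genes at least 2-fold apart named in blue and dashed lines at 2-fold. Impact, at -2.91, is the single gene below the lower line.

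Of 30 gene lists, 28 had enough measurable genes, and 6 of these had medians outside the central 95% of random lists. If each list were a random draw of genes, 1.4 would be expected. Genes of 1 list can differ together between 2 libraries, so that number is not a chance rate for these lists. The yolk sac and visceral endoderm list stood furthest out. Of its 24 measurable genes, 15 were at least 2-fold higher in matUPD18, none was at least 2-fold higher in patUPD18 and 9 lay within 2-fold. Its median log2 ratio was 1.97, above all 10000 random lists (central 95% from -0.22 to 0.18). The median was 1.23 with the floor at the 60th percentile and 1.30 without the probe sets that may match several transcripts. Besides the genes above, Rbp4 (retinol-binding protein) was 3.93-fold, Amn (amnionless, the cubilin partner) 3.92-fold and the glucose transporter gene Slc2a2 at least 5.04-fold higher. Apoa2 (1.11-fold higher in patUPD18) and the signalling gene Ihh (1.06-fold higher in patUPD18) did not share this direction. The gut endoderm and notochord list had a median of 0.35, at percentile 99.8. It shares Ttr and Spink1 with the yolk sac list, and without them its median was 0.27, at percentile 98.6. Of its 19 measurable genes, 2 were at least 2-fold higher in matUPD18, namely Ttr and Spink1, and 2 were at least 2-fold higher in patUPD18. The latter were Krt18, a simple epithelial keratin (2.82-fold), and Chrd (at least 2.36-fold).

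Genes of primitive red cells and haem synthesis were lower in matUPD18. Of 21 measurable genes, 7 were at least 2-fold higher in patUPD18, none was at least 2-fold higher in matUPD18 and 14 lay within 2-fold. The median log2 ratio was -0.71, below all 10000 random lists (central 95% from -0.25 to 0.17). Ermap, a red cell membrane protein gene, was 3.15-fold higher in patUPD18, the anion exchanger gene Slc4a1 2.63-fold, Hemgn 2.62-fold, and the erythroid transcription factor genes Gata1 and Klf1 2.58-fold and 2.54-fold. Alas2, of haem synthesis, was 2.32-fold higher in patUPD18. The embryonic globins Hba-x, Hbb-bh1 and Hbb-y were 1.84-fold, 1.51-fold and 1.34-fold higher in patUPD18 by their brightest probe sets. For Hbb-bh1 and Hbb-y these had signals of 17620 to 30979, in the upper range of the arrays, and a dimmer probe set of each differed more, with signals of 2969 and 11877 for Hbb-bh1 and of 1527 and 6224 for Hbb-y. Sptb (1.25-fold) and Car2 (1.08-fold) were higher in matUPD18, but the other measurable probe set of Sptb had the opposite direction.

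The immediate early and heat shock list had a median log2 ratio of -0.32, at percentile 0.62, and of -0.20 after loess scaling, at percentile 2.42. Of its 25 genes, 19 read higher in patUPD18 and 3 did so by at least 2-fold, namely Hspa1b, Hspa1a and Ier3 (2.38-fold). Dnajb1, a co-chaperone gene, was 1.47-fold higher in patUPD18, whereas the immediate early genes Egr1 (1.62-fold) and Egr2 (1.93-fold) were higher in matUPD18. With gene length matched, the list lay at percentile 3.30, inside the central 95%. Hox genes, which pattern the head-to-tail axis, were lower in matUPD18 in 15 of 18 cases, with a median of -0.42 at percentile 0.04. Hoxc10 was at least 2.75-fold, Hoxc8 2.57-fold and Hoxd8 2.04-fold higher in patUPD18, and Hoxb3 was 1.80-fold higher in matUPD18. The mitochondrial respiratory chain list had a median of -0.33 at percentile 0.16. Its median was -0.16 after quantile and -0.15 after loess scaling. Of its 47 genes, 40 were higher in patUPD18, and random lists of like signal also had medians below 0 (central 95% from -0.27 to -0.05). Only Cox8a (2.51-fold) exceeded 2-fold, with a log2 ratio of -0.21 by its other measurable probe set, and Cox7c was 1.83-fold higher in matUPD18. In the same pair of arrays the yolk sac list had a median of 1.97, the red cell list -0.71 and Xist a log2 ratio of 3.61.

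**Figure D3:**
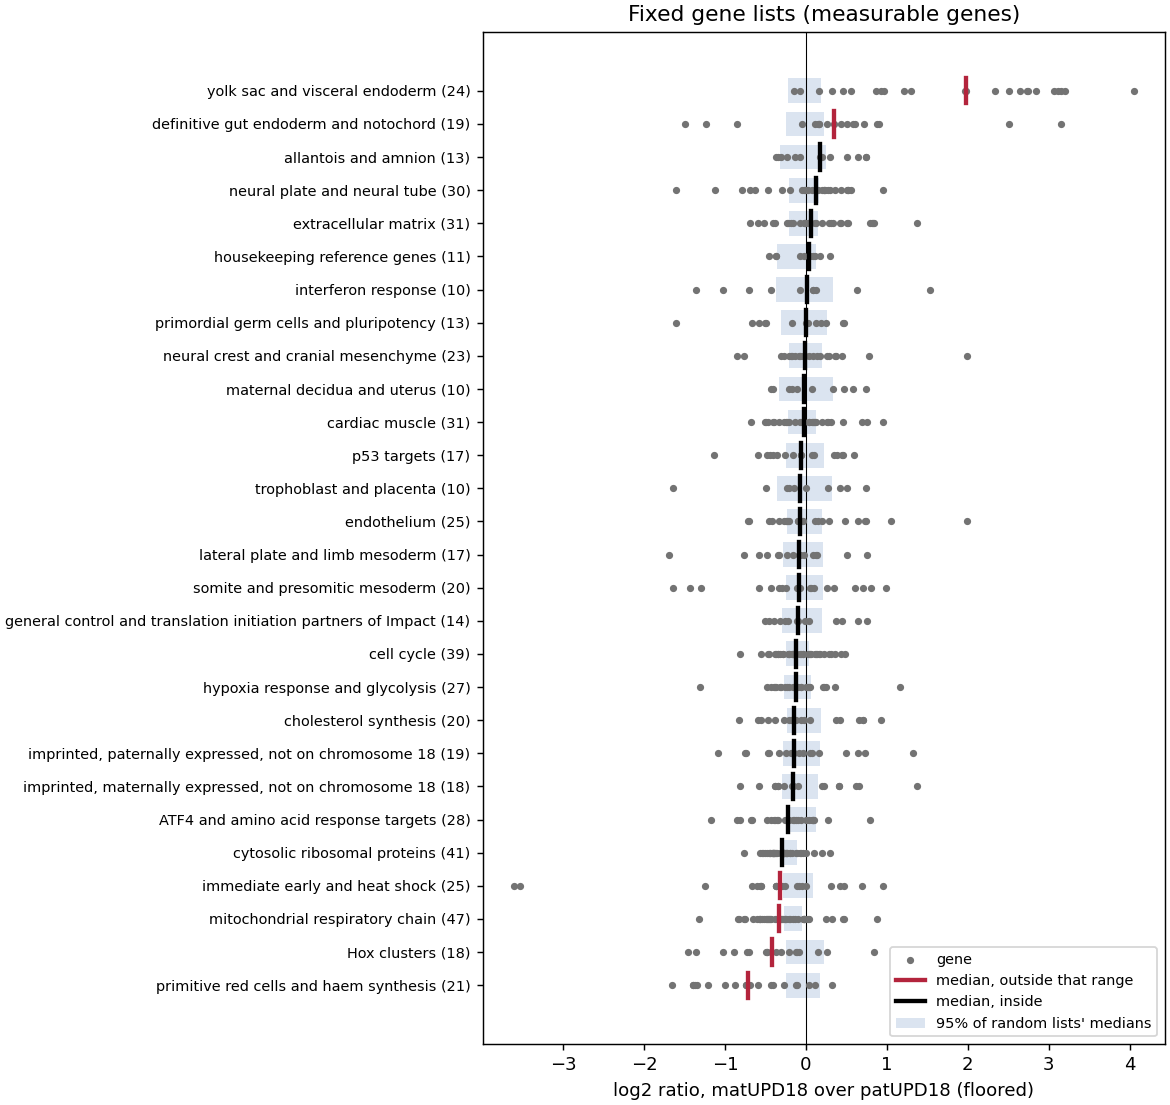
Log2 ratio of matUPD18 over patUPD18 (horizontal axis) of each measurable gene (grey points) in 28 fixed lists (rows, with the number of measurable genes), with the list median as a vertical bar and the central 95% of random lists' medians as a blue band, 1 array per genotype. The yolk sac median lies at 1.97 and the red cell median at -0.71, and 6 medians drawn in red lie outside their bands.

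Imprinted genes on other chromosomes, of which both kinds of embryo carry a maternal and a paternal copy, stayed near the rest of the genome. Among paternally expressed ones, 17 of 19 lay within 2-fold, with a median log2 ratio of -0.15 (percentile 26.0). Magel2 was 2.498-fold higher in matUPD18 and Rasgrf1 2.13-fold higher in patUPD18, while Igf2 was 1.66-fold higher in matUPD18. Among maternally expressed ones, 17 of 18 lay within 2-fold, with a median of -0.16 (percentile 25.1). Dcn was 2.59-fold higher in matUPD18 and Asb4 1.76-fold higher in patUPD18, though its other measurable probe set had the opposite direction (log2 ratio 0.30). Targets of ATF4, the transcription factor of the amino acid response, had a median of -0.22 at percentile 3.90, with 27 of 28 within 2-fold. Ddit3, at least 2.25-fold higher in patUPD18, was the exception. Rasgrf1, Dcn and Ddit3 were all among the 525 dimmest measurable genes, where they ranked 108th, 36th and 93rd in size. Ratios as large thus occurred in many other dim genes. The general control and translation initiation list had a median of -0.10 (percentile 33.6), with all 14 genes within 2-fold. It was labelled as partners of Impact when fixed, but whether each member is a partner was not tested. Of its genes, 5 were higher in matUPD18 and 9 higher in patUPD18. Eif2ak3 was 1.68-fold and Gcn1 1.57-fold higher in matUPD18, and Eif2b4 was 1.42-fold and Abcf3 1.37-fold higher in patUPD18. For Gcn1 and for Abcf3, 1 of 2 other measurable probe sets had the opposite direction.

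Most tissue lists of the embryo lay inside the range of random lists. Cardiac muscle had a median of -0.03 (percentile 62.5), with all 31 genes within 2-fold. Endothelium had a median of -0.07 (percentile 34.6), and Ets1, an endothelial and neural crest transcription factor gene, was 3.99-fold higher in matUPD18 by its brightest probe set and in the same direction by the other 2 measurable ones, with log2 ratios of 2.43 and 0.31. The neural plate and neural tube list had a median of 0.13 (percentile 94.6, or 99.6 with gene length matched). Of its 30 measurable genes, 18 were higher in matUPD18, with Egr2 (1.93-fold) and Otx2 (1.48-fold) the furthest, and 12 were higher in patUPD18. Against the direction of the median, Fabp7 (3.05-fold) and the Notch target Hes5 (2.17-fold) were higher in patUPD18. Neural crest had a median of -0.01 (percentile 55.5), lateral plate and limb mesoderm -0.08 (37.8), allantois and amnion 0.17 (93.8) and germ cells and pluripotency 0.01 (62.4). Somite and presomitic mesoderm had a median of -0.09 (percentile 33.0), with 9 genes higher in matUPD18 and 11 higher in patUPD18. In it, Cdx2 (3.13-fold), Hes7 (2.70-fold) and Msgn1 (at least 2.47-fold) were higher in patUPD18 and Dll1 was 1.99-fold higher in matUPD18. Msgn1, chosen after its value was seen, read 66.8 and 207.5 and ranked 55th in size among 525 genes of like signal.

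Lists for tissues that dissection could leave behind, other than yolk sac, did not stand out. Trophoblast and placenta had a median of -0.07 (percentile 41.1), with 9 of 10 genes within 2-fold. Maternal decidua and uterus had a median of -0.02 (percentile 48.7), with all 10 within 2-fold. Maternal blood and immune cells had 4 measurable genes, too few for a percentile, with a median of -0.16, of which Laptm5 was 1.99-fold higher in patUPD18, with 1 of its 2 other measurable probe sets in the opposite direction. Housekeeping reference genes had a median of 0.04 (percentile 91.4), cell cycle -0.12 (46.0), cytosolic ribosomal proteins -0.30 (8.43; -0.05 after quantile and -0.07 after loess scaling), cholesterol synthesis -0.14 (16.0) and extracellular matrix 0.06 (85.4). Hypoxia response and glycolysis had a median of -0.12 (percentile 46.4), in which Vegfa was 2.23-fold higher in matUPD18 and Hk1 2.48-fold higher in patUPD18. p53 targets had a median of -0.06 (percentile 38.4) and the interferon response 0.01 (62.2). The medians of the cardiac, neural crest, germ cell, interferon and cell cycle lists changed sign under at least 1 other scaling, so no direction is given for them.

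Of the genes that mark embryo sex, 4 were measurable. The Y-linked genes Eif2s3y and Kdm5d were present on both arrays, with signals of 1392 and 1448 for Eif2s3y and of 526.4 and 533.9 for Kdm5d. Uty was 1.97-fold higher in matUPD18. Xist read 1568 in matUPD18 and 128.1 in patUPD18, the latter below the measurable limit.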

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

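Gene length matching and leaving out yolk sac or red cell genes were chosen after seeing the data. With 1 array per genotype, no array could be left out, and the number of arrays limits every value here. No paired analysis was possible because each genotype has a single array. Of the alternative values of the main results, 53 stayed close to the main value and 8 moved. Counts within 1.5-fold of the main count were called close. Of the 53, 12 had no floor or one at the 20th percentile and could not move. The chromosome 18 median with gene length matched, also among the 53, could not move either, since matching changes only the random lists. Its percentile went from 99.7 to 97.3. The Impact log2 ratio moved to -1.26 as the median over its 2 measurable probe sets, which have opposite directions, and lay between -2.95 and -2.90 otherwise. The count of genes at least 2-fold higher in matUPD18 (283) became 1045 at a threshold of 1.5-fold, that of genes at least 2-fold higher in patUPD18 (187) became 916, and chromosome 18 genes at least 2-fold apart (12) became 55; a threshold of 3-fold gave 48, 28 and 6, by construction. A floor at the 60th percentile gave 78 genes higher in patUPD18 and 189 higher in matUPD18 (70.8% of those apart, against 60.2%), since by construction it shrinks folds against low signals. Removing the floor or setting it at the 20th percentile cannot change the 2-fold counts, left every list median as it was and tests nothing about them. Under the 3 other scalings the genes higher in matUPD18 numbered 255 to 297 and those higher in patUPD18 181 to 232. Without the yolk sac list, 268 genes were higher in matUPD18 and 10 were apart on chromosome 18; without the red cell list, 180 were higher in patUPD18. Between 6 and 7 lists lay outside the central 95% in all alternatives. The yolk sac, red cell, Hox, gut endoderm, respiratory chain and heat shock lists were outside in 6 scaling, floor and probe set alternatives. These leave out no floor and the floor at the 20th percentile, which could not move them. Median centring, 1 of the 6, shifts all genes alike and so tests little about a list's place among random lists. After loess scaling the heat shock list lay at percentile 2.42, too close to the limit of 2.5 to decide. The yolk sac median was 1.23 with the floor at the 60th percentile and 1.30 without _s_at and _x_at probe sets. The respiratory chain median was -0.16 and -0.15 after quantile and loess scaling. With gene length matched, the heat shock list left and the neural tube list entered. Cytosolic ribosomal proteins were outside in 2 of the 6. For the other named genes, 9 alternative values in 8 genes had the opposite sign to the main value, and 2 of these genes, Gpaa1 and Ddit3, were at least 2-fold apart. The Gpaa1 log2 ratio became 0.060 with the median over its probe sets, and the Ddit3 log2 ratio 0.0043 with the floor at the 60th percentile, where both its signals sat at or near the floor. The other genes were less than 2-fold apart: the Stard4 log2 ratio became 0.40 and that of Csf1r -0.05 with the median over probe sets, those of Shmt2 0.55 and Hoxc6 -0.64 without _s_at and _x_at probe sets, that of Pgk1 0.02 after quantile scaling, and that of Ss18 0.08 and 0.10 after quantile and loess scaling.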

Other observations

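The tests of explanations in this part were chosen after the patterns had been seen; for the gene length match of chromosome 18, also chosen then, the outcome itself had not been seen. Of 365 measurable X-linked genes, 29 (7.95%) were at least 2-fold apart, at percentile 99.8 of random lists (central 95% from 10 to 24), and 23 of them were higher in matUPD18. X was not alone in this, since chromosome 6 also lay above its range (34 genes, percentile 98.9, central 95% from 15 to 32), and chromosomes 5 (15 genes, percentile 0.70) and 8 (13 genes, percentile 0.725) lay below theirs. Among the X-linked genes, Kdm6a, a histone demethylase gene known to escape X inactivation, was 2.55-fold higher in matUPD18, and Ftx, a non-coding gene of the X inactivation centre, was 2.25-fold higher. Ddx3x, also known to escape, was 1.48-fold higher by its brightest probe set, with log2 ratios of 0.29 and 1.23 by its other measurable ones. The log2 ratios of Eif2s3x (0.38) and Kdm5c (0.16) by their brightest probe sets lay within the 0.44 between probe sets of a gene. Their other measurable probe sets gave 0.85 and -0.19 for Eif2s3x and from -0.81 to 0.40 for Kdm5c. These 5 genes were chosen after their values were seen and were not tested as a set.

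Probe sets with no gene in the annotation used here added 148 at least 2-fold higher in matUPD18 and 42 at least 2-fold higher in patUPD18, of 2278 measurable ones. The largest differences were at least 6.62-fold higher in matUPD18 and at least 4.62-fold higher in patUPD18. Their chromosomes were not assigned here.

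The clearest pattern beside Impact is higher yolk sac endoderm genes in matUPD18, led in signal by Afp and Ttr, beside lower red cell genes; 3 of the 24 yolk sac genes are also on other lists. Carry-over of whole yolk sac into the matUPD18 RNA would bring its blood, yet the red cell list had a median log2 ratio of -0.71, below all random lists, which argues against that as the sole explanation. That median was known when the prediction was written, and it cannot tell yolk sac blood from the embryos' own. Carry-over of whole yolk sac together with another difference in blood content is therefore not excluded. Carry-over of endoderm without its blood stays open, since no value here sets the embryo's own expression of these genes apart. A less advanced stage of the matUPD18 embryos, which might also lower Hox and red cell genes, predicts lower cardiac genes, and the cardiac median lay at percentile 62.5, with members on both sides, which does not decide. An effect of the parental origin of chromosome 18 also stays open and was not tested, with 1 array per genotype.

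Xist was 12.2-fold higher in matUPD18 while Y-linked genes were present on both arrays. RNA from female embryos alone is argued against by the Y-linked genes, whose median matUPD18 signal was 2.65 above the floor on the log2 scale. A larger share of female embryos in the matUPD18 RNA may account for Xist, and it predicts lower Y-linked signals there. The 3 measurable Y-linked genes had log2 ratios of -0.056 (Eif2s3y), -0.020 (Kdm5d) and 0.98 (Uty), so the predicted fall was not seen. Their median of -0.020 lay within the 0.44 between probe sets, which is a spread of single probe sets. With 3 genes and 1 array per genotype, a larger share of female embryos stays open. The labels give neither the sex nor the number of the embryos.

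The slightly positive median of chromosome 18 may follow gene length. Across genes, which are not independent replicates, the log2 ratio had a Spearman's rho of 0.21 with gene length, from a median of -0.20 in the shortest of 10 equal groups to 0.09 in the longest. Matched on signal and length, chromosome 18 lay at percentile 97.3, with a simulation error of 0.16, so close to the upper limit of the central 95% that the test does not decide. After matching, 5 of the 8 chromosomes outside before were still outside. Strain differences on chromosome 18 between the parents were not tested.

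A hypothesis from the known role of Impact as an inhibitor of GCN2 is that embryos with little Impact may carry more transcript of amino acid response genes. The ATF4 target list lay at percentile 3.90, with 20 of 28 genes lower in matUPD18, so no such excess was seen in these arrays, but the median stayed inside the central 95%, and heat shock genes differed between the arrays as well.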
